A study of Mus musculus with 10 samples.

How the data were processed

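The study deposited single-cell RNA counts of sorted CD11b+ cells from mouse lungs (C57BL/6J, viable by 7AAD exclusion, per the labels) for 10 samples, and counts of surface antibodies for 8 of them. The deposited RNA values were raw UMI counts per gene and cell, made with Cell Ranger 6.0.1 against mm10, per the submitters' processing notes. The gene annotation release was not given in the sources used here. The deposited antibody values were raw counts of 20 antibody tags per cell. The authors also deposited a text label per cell, naming its type or neutrophil state, by a method not stated in the sources used here. Labels were taken as deposited. Gene coordinates and transcript lengths came from GENCODE M21, which is on the same build, and 95.7% of genes had a length.

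Groups came from the labels, with 2 healthy, 4 untreated KP and 4 treated samples. Treated replicates 1 and 3, and 2 and 4, turned out to hold the same cells. Cell totals of the shared barcodes correlated at 0.9999 and 0.9995, and 96.85% and 97.64% of shared cells had the same state label. The spread between runs of a pair was 0.484 of that expected from counting alone (chi-squared per degree of freedom), against 37.6 to 38.8 across the pairs. Each pair was averaged, leaving 8 independent libraries. The design had planned 4 treated libraries, so tests with 2 treated libraries replaced those planned with 4, and the smallest exact permutation p rose to 0.0667. Cells with a neutrophil label whose neutrophil flag was false were left out (119 in the deposited samples). Types with too few cells in all libraries (Mac3, pDC, T2 and T3) were not compared.

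Sums of UMIs per library and cell class were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, filterByExpr) with all 3 groups in 1 fit and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Neutrophils were all deposited states together. Another class was tested for treatment where at least 20 cells were present in both treated and in at least 3 KP libraries, which left Mono3, and Mac1 with 3 KP libraries. KP against healthy lung was tested in these classes where both healthy libraries held at least 20 cells, which left Mono3. Mono1 and DC2 had enough healthy and KP cells but too few in 1 treated library, and were not tested. The design had asked for 3 libraries in both groups, which no class could meet once the treated runs were merged. Shares of cells were compared by an exact permutation test of library labels, adjusted over 15 types or 7 states. Antibody counts were scaled to 10000 per cell, 1 was added, log2 was taken, and the mean over neutrophils per library was tested with limma 3.58.1. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Differences between cell classes in the treatment change were tested with limma on log2 CPM (prior count 2) of neutrophils minus the other class in each library.

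The 19 gene lists and the rule for named genes were fixed before the data were examined. The lists held 261 genes, of which 3 were not in the gene table. They covered interferon-stimulated genes, interferon-gamma response genes, MHC class I and class II presentation, specific granules, azurophil granules and progenitors, SiglecF-high tumour neutrophils, cytokines and NF-kB targets, hypoxia and glycolysis, the cell cycle and dissociation stress. The other lists held markers of T cells, B cells, NK cells, mononuclear phagocytes, alveolar macrophages, epithelial or tumour cells, and red cells or platelets. Some genes sat in several lists, such as Chil3 in the alveolar macrophage and the specific granule lists, and Siglecf was a member of the list named after it. Named were the 8 largest rises and 8 largest falls among called genes with mean log2 CPM of at least 4 whose libraries were fully separated. From each list the up to 3 called members with the highest mean log2 CPM were named, or 2 members where none was called. Siglecf, Cd40, Irf1 and Csf3r were given in neutrophils whatever their values. In addition, 1 list and some single genes and antibodies are not reported here. Predicted genes were counted but not named, and in Mono3 and Mac1 uncalled members of lists appear as counts alone. Genes said to be chosen after their values were seen lie outside this rule.

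Where a group had 0 counts the ratio was bounded with 3 counts over the group, and where it had 1 to 3 the ratio of counts was given with an exact 95% interval. Intervals of shares were exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error alone. The sensitivity of the gene test was checked on simulated counts in which 200 genes were changed. The counts were drawn with the real library sizes, 1 mean per gene pooled over all libraries, and 1 spread for all genes. Changed genes were picked among those with more than 5 counts expected in the median library. The shares recovered are of the changed genes that passed the filter, so they do not cover genes with fewer counts or a larger spread. For treated against KP neutrophils, with 4723 genes tested, 61.8% of changes of 1 on the log2 scale and 100% of changes of 2 were recovered, with 5 false calls. For KP against healthy neutrophils, with 4726 genes, the shares were 35.6% and 86.4%, with 1 false call. In Mono3 they were 56.3% and 97.8% for treatment (802 genes, 4 false calls) and 43.0% and 89.8% for KP against healthy (783 genes, 2 false calls). In Mac1 they were 31.2% and 88.4% (624 genes, 4 false calls).

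The alternatives were DESeq2 1.42.0, DESeq2 size factors (RLE) in edgeR, no filter on low counts, the replicate number as a block, each library left out, the libraries with antibody counts alone, the 2 compared groups alone, and cells with at least 1000 UMIs. For lists they were camera with an estimated correlation and fry, for shares edgeR on cell counts, for antibodies centred log ratios, summed counts and a minimum of 50 counts per cell, and for differences between classes a prior count of 0.5. Added after the data were seen were the 4 treated samples counted as 4 libraries, 1 run of each pair, treated sums thinned to the KP totals, single neutrophil states, and antibody counts thinned to 100 per cell. Scrublet called at most 0.441% of cells in any sample as doublets, too few for a working caller unless doublets had been removed before deposition, which is not given in the sources used here. No doublets were removed. Computations used R 4.3.3 and Python 3.11.15, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9.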

Results

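Viable CD11b+ cells sorted from mouse lungs were counted for RNA and for surface antibodies cell by cell, in healthy lungs, in KP lung tumours grown for 31 days, and in KP tumours collected 2 days after agonist anti-CD40 at 5 mg/kg. KP, named KP19 in the sample titles, is a mouse model of lung adenocarcinoma, and anti-CD40 is an antibody that triggers CD40 on antigen-presenting cells. Healthy lung gave 2 independent libraries with 3512 cells, untreated KP tumours 4 libraries with 4892 cells, and treated tumours 2 libraries. The 4 deposited treated samples held the same cells in pairs. Replicates 1 and 3 shared 8824 cell barcodes, 99.4% of the smaller sample, and replicates 2 and 4 shared 7808, or 98.9%. The other 43 pairs of samples shared at most 4 barcodes. Each pair was averaged and counted as 1 library.

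Depth differed with treatment. The median number of unique transcripts (UMIs) per cell was 604 to 741 in healthy libraries, 490 to 537 in KP libraries and 2909 to 4135 in treated samples. No healthy or KP cell held more than 2641 UMIs, and no treated cell held fewer than 1695. Whether cells outside these ranges were left out before deposition is not given in the sources used here, so all shares of cells are shares of the deposited cells. In neutrophils the library totals ran from 174528 to 411624 UMIs in healthy lung, from 322951 to 777497 in KP tumours and from 19731856 to 22648231 in treated samples. No library batch is given in the sources used here. No untreated library had the depth of the treated ones, so effects of depth or of library making, if they differed, went together with treatment. The labels do not say whether replicates came from separate mice, so p-values measured only the spread between libraries.

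The comparison of KP tumours with healthy lung asked how the tumour site changed neutrophils and other myeloid cells. KP cells came from tumour nodules and healthy cells from normal lung, so the tissue sampled and the tumour went together. In KP neutrophils Siglecf, a sialic acid-binding receptor known from long-lived tumour neutrophils, rose 8.36-fold over healthy neutrophils (log2 change 3.06, SE 0.53; 4 against 2 libraries). Csf3r, the receptor for the neutrophil growth factor G-CSF, fell by 1.49 on the log2 scale (SE 0.14). Cd63, a granule membrane protein, rose with a log2 change of 1.37, and Mif, a macrophage migration inhibitory cytokine, with 3.78 (SE 0.33). Adjusted p-values were 0.000225 for Siglecf, 4.64e-07 for Csf3r and 2.37e-07 for Mif by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Every KP library lay on the same side of both healthy libraries for Siglecf and Csf3r.

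Siglecf lies on chromosome 7 from 43351341 to 43359531 of mm10 and Csf3r on chromosome 4 from 126024550 to 126044440. Irf1, an interferon-induced transcription factor, lies on chromosome 11 from 53770014 to 53778374, and Cd40, the target of the antibody, on chromosome 2 from 165055627 to 165072948. All 4 genes are protein-coding and on the plus strand. Cd40 was too rare in neutrophils to be tested, with 56 of 42309755 UMIs in treated libraries and 0 of 2159699 in KP libraries.

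The largest rises in KP neutrophils were in genes that healthy neutrophils hardly showed. Gpr171, a receptor coupled to G proteins, had 300 UMIs in KP neutrophils and 0 in healthy ones, a rise of at least 27.1-fold. P2ry14, the receptor for UDP-glucose, had 262 against 0, at least 23.7-fold. The ratio was 173 for Car4, a membrane carbonic anhydrase, with a counting interval from 30.9 to 6828. It was 93.9 for Tnfrsf13b, a receptor for B-cell survival factors (16.7 to 3720), 88.5 for Ms4a6d, a membrane protein of macrophages (15.8 to 3505), 79.3 for Ddt, a relative of Mif (14.1 to 3141), and 72.5 for Prss2, a trypsin (20.0 to 600). The steepest falls were in Gpr141, an orphan receptor (fell by 3.66, SE 0.39), Mmp8, a collagenase of neutrophil granules (fell by 3.24, SE 0.24), and Padi4, the enzyme that citrullinates histones (fell by 3.12). Scnn1a, a sodium channel subunit, fell by 3.24, Rnf144a, a ubiquitin ligase, by 3.23, and Tmem71 by 3.21.

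Genes of tumour neutrophils were higher in KP tumours. Of 18 measured genes of SiglecF-high tumour neutrophils, 16 rose and 0 fell, with a median log2 change of 2.05, and 16 rose when adjusted over the list alone. Cstb, an inhibitor of lysosomal proteases, rose with a log2 change of 2.16 (SE 0.20), and Ccl4, a chemokine, with 2.39 (SE 0.24). The list moved up by camera (adjusted p = 1.7e-14), and its adjusted p = 0.109 with an estimated correlation. The list came from earlier work on neutrophils in mouse tumours, not from these libraries. Retnlg, a resistin-like secreted protein, fell by 2.91 (SE 0.20), and S100a8 and S100a9, the calprotectin subunits, fell by 1.15 and 1.40.

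Interferon-stimulated genes were lower in KP neutrophils. Of 32 measured, 0 rose and 17 fell, and over the list alone 1 rose and 18 fell, with a median of −1.21 and adjusted p = 0.00022 by camera (adjusted p = 0.232 with an estimated correlation). Ifitm3, an antiviral membrane protein, fell by 1.47 (SE 0.17), Isg15, a ubiquitin-like protein, by 1.36, and Trim30a, a regulator of innate signalling, by 0.95. Of 12 interferon-gamma response genes 1 rose and 3 fell, and the list was not called by camera (adjusted p = 0.311). Fgl2, a fibrinogen-like protein, fell by 1.72 (SE 0.15), Irf1 fell by 0.92 (SE 0.22), and Socs1, which restrains cytokine signalling, rose with 1.65. Of 16 genes of MHC class I presentation 2 rose and 6 fell (camera adjusted p = 0.0845), among them H2-D1 (fell by 1.69), B2m (fell by 0.91) and H2-K1 (fell by 0.73). None of 5 MHC class II genes was called. Their median was 0.16 and their mean −0.19, with camera adjusted p = 0.893, Cd74, the invariant chain, at 0.16 and H2-Eb1 at −0.95.

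Of 19 genes of glycolysis and hypoxia 11 rose and 2 fell in KP neutrophils (12 and 3 over the list alone), with a median of 0.95 and camera adjusted p = 0.0174 (adjusted p = 0.26 with an estimated correlation). Gapdh and Aldoa, glycolytic enzymes, rose with 0.71 and 0.63. Of 12 immediate-early and heat-shock genes, which tissue dissociation can induce, 2 rose and 8 fell, with a median of −1.08 and camera adjusted p = 5.23e-06 (adjusted p = 0.157 with an estimated correlation). Dusp1, a phosphatase, fell by 2.17 (SE 0.15), and the transcription factors Fos and Junb by 1.74 and 1.09.

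Other lists were mixed. Of 16 cytokine and NF-kB target genes 8 rose and 5 fell (8 and 6 over the list alone), with a median of 1.04 and camera adjusted p = 0.0845. Cxcl2, a neutrophil-attracting chemokine, rose with 1.66 (SE 0.14), Il1b, an inflammatory cytokine, fell by 0.52, and Ptgs2, a prostaglandin synthase, fell by 1.31. Of 13 specific granule genes 1 rose and 7 fell (8 over the list alone), with a median of −1.35 and camera adjusted p = 0.0845. Cd177, an adhesion protein of neutrophils, rose with 1.83, while Lcn2, an iron-scavenging granule protein, fell by 1.35 and Lyz2, a lysozyme, by 0.73. Of 4 genes of azurophil granules and progenitors 3 rose and 1 fell, with a median of 2.21, or 1.76 with bounds for genes at 0 counts, and camera adjusted p = 0.119. Ctsc, a protease that activates granule enzymes, rose with a ratio of 13.3 (counting interval 4.46 to 65.2), Calr, a chaperone, with 1.21, and Srgn, a granule proteoglycan, fell by 0.33. Of 3 cell cycle genes Pcna and Tubb5 rose with 1.35 and 1.86 and Hmgb2 fell by 1.75. Their median was 1.35 and their mean 0.49, and camera pointed down (adjusted p = 0.668).

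Few markers of other cells passed the filter in neutrophils. The B-cell marker Ighm fell by 2.60 (camera adjusted p = 0.0174 for this list of 1 gene; adjusted p = 0.157 with an estimated correlation). Of 7 mononuclear phagocyte genes 1 rose and 1 fell (camera adjusted p = 0.668), Adgre1, which encodes F4/80, with 1.91 and Ly6c2, a surface protein of monocytes and some neutrophils, which fell by 2.98. Of 2 alveolar macrophage markers, Car4 was called over all genes and 2 over the list alone, with camera adjusted p = 0.0453 (adjusted p = 0.232 with an estimated correlation). No marker of T cells, NK cells, epithelial cells, red cells or platelets passed the filter in neutrophils.

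Over all 5613 genes tested in neutrophils, 989 were higher and 1252 lower in KP tumours by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2732 passed without adjustment. KP and healthy libraries were fully separated for 58.9% of genes, where chance gives 13.3%. The count rested on the healthy libraries, with 761 higher and 890 lower without healthy replicate 1 and 499 and 579 without healthy replicate 2. The median over all genes was −0.028 with TMM scaling and 0.11 with RLE or DESeq2 size factors.

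Calls of single named genes rested on the healthy libraries as well. Without healthy replicate 1 the calls of Irf1 (−0.73), Socs1, H2-K1 (−0.61), Lcn2 (−0.82), Srgn, Il1b (−0.48) and Aldoa (0.57) were lost. Without healthy replicate 2 those of Trim30a (−0.83), Irf1 (−0.88), Socs1 (2.69), H2-K1 (−0.59), Lyz2 (−0.46), Srgn, Calr (1.27), Il1b (−0.30), Pcna (1.40) and Adgre1 (1.62) were lost, and the call of Srgn was lost with each KP library left out in turn too.

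**Figure D1:**
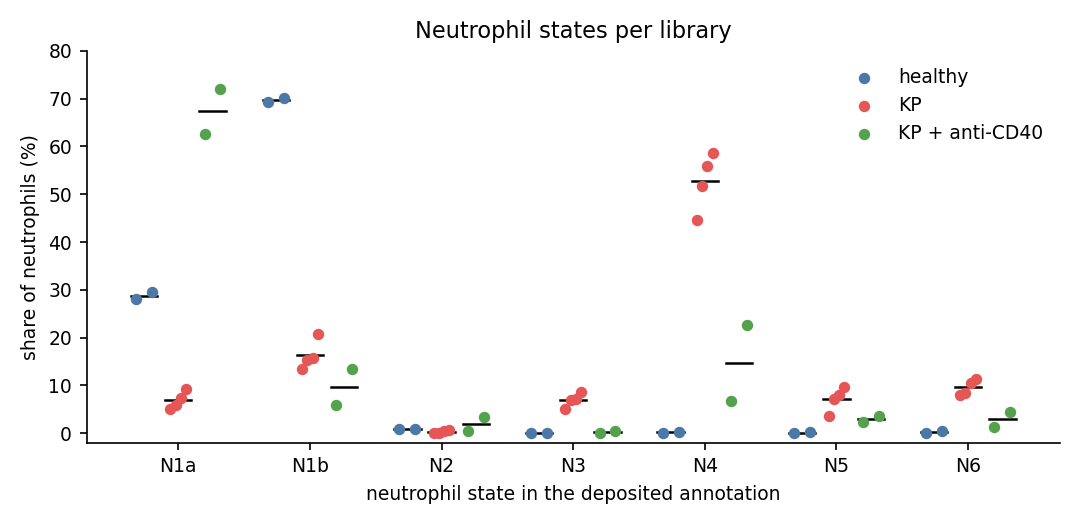
Share of neutrophils in each of 7 deposited states (percent, vertical axis) in healthy, KP and treated libraries, with 1 point per independent library and lines at group means. State N4 was 52.8% of neutrophils in KP tumours and 0.175% in healthy lung.

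Neutrophils were 36.6% ± 13.3 (SD, n = 2) of CD11b+ cells in healthy lung and 79.3% ± 3.88 (n = 4) in KP tumours. The deposited labels divide them into states N1a to N6. N1b was 69.7% of healthy and 16.3% of KP neutrophils, N1a 28.8% ± 0.943 and 6.90% ± 1.82, and N4 0.175% and 52.8% ± 6.09. N3 was absent from the healthy libraries, with 0 of 414 and 0 of 917 cells, which allows up to 0.725% and 0.327%, and was 6.96% of KP neutrophils. N5 was 0.109% against 7.14%, N6 0.218% against 9.59%, and N2 0.974% against 0.339%. Every state separated KP from healthy libraries. For 6 states the p was the smallest that 4 against 2 libraries allow (exact permutation p = 0.0667, adjusted 0.0778), for N2 it was 0.133 (adjusted 0.133), and none was called. With edgeR on the cell counts, 6 states were called.

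The shares of other CD11b+ cells differed as well. Mono1 was 21.8% of healthy and 4.07% of KP cells, Mono2 17.0% and 1.09%, NK cells 10.5% and 1.17%, and MonoDC 4.17% and 0.972%. Mono3 was 2.19% against 3.88% and Mac2 0.0909% against 0.963%. Mac4 was 0.339% against 0.0276% and basophils 0.375% against 0.0143%. These 8 types and neutrophils separated the groups at the smallest p (exact permutation p = 0.0667, adjusted 0.111). Mac1 (0.930% against 1.97%) and DC2 (1.89% against 3.42%) separated them too, at larger p (at least 0.133, adjusted 0.182). None was called by that test, while edgeR on cell counts called Mono2 (adjusted p = 0.0201), NK cells (0.0201) and Mac2 (0.0414).

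On the surface, SiglecF rose in KP neutrophils with a log2 change of 4.03 (SE 0.47; n = 2 in each group with antibody counts; adjusted p = 0.000926 by limma). Of 20 antibodies 15 were called by limma. The co-receptor CD14 rose from 6.08 to 9.18 log2 counts per 10000, the adhesion molecule ICAM1 with 2.42, the checkpoint ligand PDL1 with 2.24 and the chemokine receptors CXCR2 and CXCR4 with 2.09 and 1.17. F4/80, CD38 and MHC class II rose with 1.67, 1.13 and 0.68. The integrin CD11a fell by 1.51, ICAM2 by 1.08, Ly6G by 1.01 and CD49d by 0.78. With 2 against 2 libraries the smallest exact permutation p was 0.333.

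The comparison of treated with untreated KP tumours asked how anti-CD40 changed the tumour's neutrophils and other myeloid cells. All 32 measured interferon-stimulated genes rose in treated neutrophils, with a median log2 change of 3.63 (2 treated against 4 KP libraries). Ifitm3 rose with 3.89 (SE 0.16; adjusted p = 8.01e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Isg15 with 2.87 (SE 0.14; adjusted p = 9.36e-11). Siglecf fell by 1.53 (SE 0.29; adjusted p = 0.000369), and Csf3r stood at 0.27 (SE 0.14; adjusted p = 0.123), not called. Both treated libraries lay on the same side of all 4 KP libraries for Ifitm3, Isg15 and Siglecf. All 32 interferon-stimulated genes were called over the list alone too, and camera gave adjusted p = 5.11e-54 (adjusted p = 0.0535 with an estimated correlation). The filter on low counts could admit a gene through the treated libraries alone, and a member admitted that way was bound to rise.

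The largest rises in treated neutrophils were in Ifitm6, an interferon-induced membrane protein (6.94, SE 0.22, or 123-fold), Ly6c2 (6.26, SE 0.23), Ly6g, which encodes the neutrophil marker Ly6G (5.82, SE 0.23), and Mmp8 (5.70, SE 0.22). Ngp, a granule protein, rose with 5.67 (SE 0.71), H2-Q7, a non-classical MHC class I molecule, with 5.39 (SE 0.42), and Ifit1 and Ifit3, sensors and blockers of viral RNA, with 4.99 and 4.90. Ifitm6 stood at 12.40 ± 0.42 log2 CPM in treated and 5.48 ± 0.49 in KP libraries (SD). The steepest falls were in Dynlt1b, a dynein light chain (fell by 4.23, SE 0.50), Gstp1, a glutathione transferase (fell by 3.31, SE 0.33), AC160336-1 (fell by 3.21) and Hist2h2aa1, a histone (fell by 3.12).

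In the treated libraries the median change of short transcripts lay below that of long ones in neutrophils, Mono3 and Mac1. The median log2 change of genes up to 600 bases minus that of genes over 1000 bases was −1.11 (SE 0.19) in neutrophils, −0.63 (SE 0.16) in Mono3 and −0.58 (SE 0.25) in Mac1. All SEs of this difference came from the spread over genes, taken as independent. They do not measure the spread between libraries. In neutrophils 10 short genes were higher and 60 lower of 84, against 1366 and 1015 of 4954 long genes. In Mono3 4 short genes were higher and 21 lower of 62, and in Mac1 1 was higher and 0 lower of 64. Between KP and healthy libraries the same difference was 0.59 (SE 0.25) in neutrophils and 0.40 (SE 0.16) in Mono3. Of the named falls with treatment whose length was known, 3 of 3 in neutrophils, 1 of 4 in Mono3 and 2 of 4 in Mac1 were of transcripts up to 1000 bases, against 3 of 8, 3 of 8 and 2 of 7 of the named rises.

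**Figure D2:**
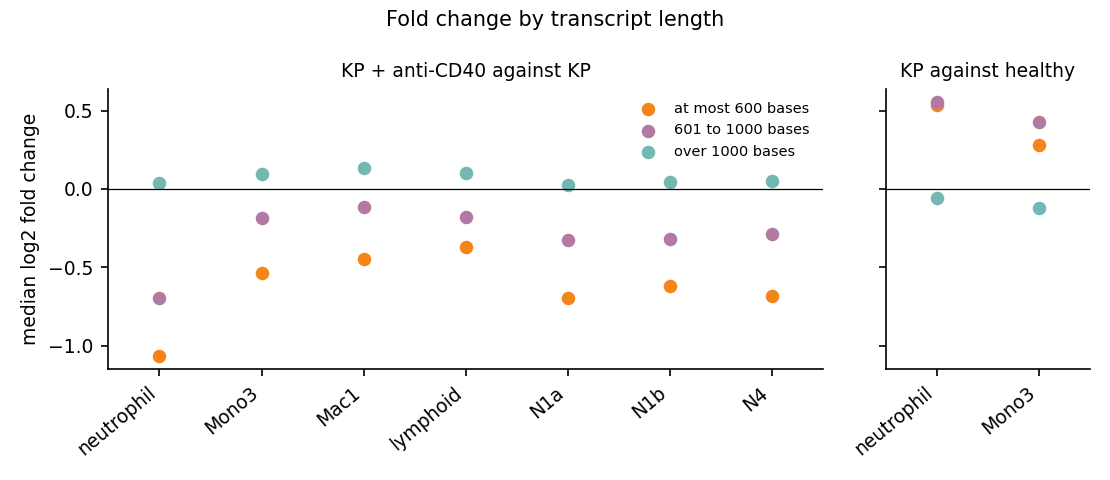
Median log2 change (vertical axis) of genes with transcripts up to 600, between 600 and 1000, and over 1000 bases (points), per cell class, for treated against KP (left) and KP against healthy (right). In treated neutrophils the medians were −1.07, −0.69 and 0.041.

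Genes that present peptides on MHC class I rose with the interferon-stimulated ones, 14 of 16 up and 0 down, with a median of 2.14 and camera adjusted p = 4.03e-14 (14 over the list alone; adjusted p = 0.122 with an estimated correlation). H2-D1 rose with 2.09, B2m with 2.19 and H2-K1 with 3.19. Of 12 interferon-gamma response genes 8 rose (10 over the list alone), with a median of 2.08 and camera adjusted p = 9.44e-06 (adjusted p = 0.122 with an estimated correlation). Among them were the guanylate-binding proteins Gbp2 (4.38) and Gbp7 (2.63) and Irf1 (1.64, SE 0.17). All 5 MHC class II genes fell, with a median of −1.86 and camera adjusted p = 0.000413 (adjusted p = 0.0892 with an estimated correlation), Cd74 by 1.74 (SE 0.17), H2-Aa by 2.22 and H2-Ab1 by 1.86. Apoe and Adgre1, genes of mononuclear phagocytes, fell by 1.64 and 1.90 in the same neutrophil sums, and DC2 was 0.358% of treated and 3.42% of KP cells, so whether the class II transcripts came from neutrophils is left open.

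In treated neutrophils Retnlg rose with 4.31 (SE 0.21), S100a8 with 1.03 and S100a9 with 1.65. Of 13 specific granule genes 12 rose and 0 fell (12 over the list alone), with a median of 3.72 and camera adjusted p = 2.3e-13 (adjusted p = 0.0892 with an estimated correlation), Lcn2 with 4.36 (SE 0.26), Cd177 with 1.41 and Lyz2 with 1.46. Of 18 SiglecF-high genes 1 rose and 12 fell (1 and 12 over the list alone), with a median of −0.81 and camera adjusted p = 0.00314 (adjusted p = 0.273 with an estimated correlation). Cstb fell by 1.13, Ccl3, a chemokine, by 0.81 and Ccl4 by 1.03.

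Within single states part of these genes stood on the other side of 0, in comparisons chosen after the data were seen. S100a8 was called lower in N1a (−0.42) and N1b (−0.25) by edgeR's quasi-likelihood test, and stood at −0.22 in N4, not called. Cstb was called higher in N1b (0.64) and stood at 0.33 in N1a, not called. Ccl4 stood at 0.55 in N1b and 0.21 in N4, neither called. Csf3r fell by 0.65 in N1a, 0.45 in N1b and 0.55 in N4. Of the SiglecF-high list 4 rose and 1 fell of 10 in N1b, with a median of 0.48, and 3 rose and 2 fell of 17 in N4, with −0.11, and neither list was called by camera. Ccl3 was called higher in N1b (1.17) and N4 (0.73) and Il1rn in N1b (0.81), where both fell over all neutrophils. Dusp1 was called lower in N1a (−0.57) and stood at −0.31 in N1b, not called. In cells with at least 1000 UMIs Ctsc was called lower (−1.10). There S100a8 stood at −0.16, Lyz2 at −0.50, Ccl4 at 0.98 and Ptgs2 at 0.31, none of them called. This minimum removed no treated cell and left 35 to 69 neutrophils per KP library, with 38 N4 and 2 N1a cells over all KP libraries. It thus changed the mix of KP states along with the depth. The call of Siglecf was lost within N4 (−0.23). Interferon-stimulated genes rose within each state, 15 of 15 in N1a, 19 of 19 in N1b and 20 of 22 in N4. Members that passed the filter through the treated libraries alone were bound to rise, so these shares are partly set by the filter.

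Other lists showed smaller or mixed changes in treated neutrophils. Of 16 cytokine and NF-kB genes 3 rose and 7 fell (3 and 7 over the list alone), with a median of −0.37 and camera adjusted p = 0.426. Cxcl2 rose with 0.54, Il1rn, the interleukin 1 receptor antagonist, fell by 0.61 and Ptgs2 by 0.94. Of 19 hypoxia and glycolysis genes 3 rose and 7 fell, with a median of −0.36 and camera adjusted p = 0.379, Pkm, a glycolytic kinase, with 0.93, Mif falling by 1.97 and Eno1, an enolase, by 0.73. Of 12 dissociation stress genes 5 rose and 3 fell, with a median of 0.12, a mean of −0.037 and camera up at adjusted p = 0.806. Junb rose with 0.52, Fos with 0.98 and Dusp1 with 0.95. Of 3 cell cycle genes Hmgb2 rose with 1.41, Tubb5 fell by 1.32 and Pcna by 0.94 (camera adjusted p = 0.917). Of 4 azurophil and progenitor genes Ctsc alone rose, with 0.50 (adjusted p = 0.032 by edgeR's quasi-likelihood test). Its call was lost over the list alone and with each KP library left out in turn, and camera gave adjusted p = 0.891.

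Markers of other cells moved in both directions. Of 7 mononuclear phagocyte genes 1 rose and 4 fell, with a median of −0.91 and camera adjusted p = 0.806. Ly6c2 rose, Apoe, a lipid carrier of macrophages, fell by 1.64 and Adgre1 by 1.90. Chil3, a chitinase-like protein that sits in the alveolar macrophage and the specific granule lists, rose with 4.10 and Car4 fell by 1.60 (camera adjusted p = 0.806). Ighm, alone of the B-cell markers, stood at 0.50 (adjusted p = 0.0935 by edgeR's quasi-likelihood test), not called, with camera adjusted p = 0.806.

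**Figure D3:**
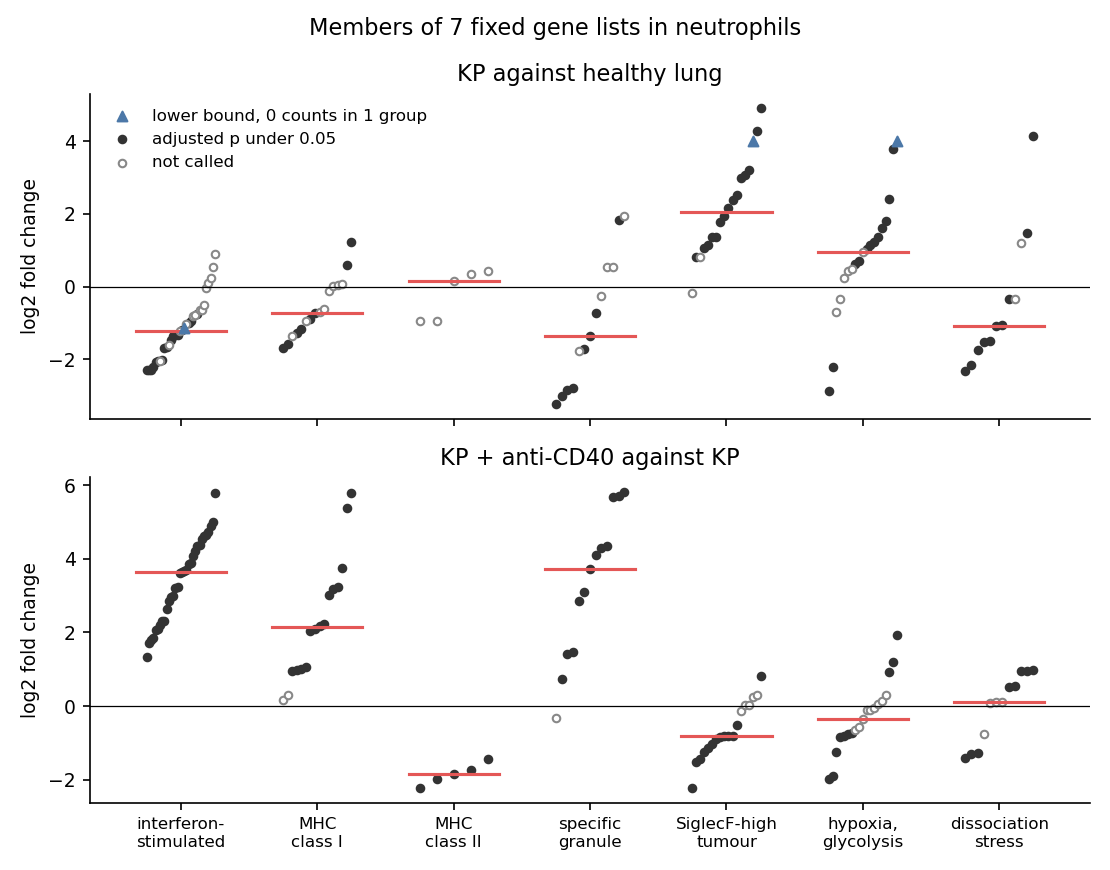
Log2 change of every measured member of 7 fixed lists in neutrophils, KP against healthy (top) and treated against KP (bottom). Filled points were called by edgeR's quasi-likelihood test, open points were not, triangles are bounds for genes with 0 counts in 1 group, and red lines are medians, 3.63 for interferon-stimulated genes in treated neutrophils.

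**Figure D4:**
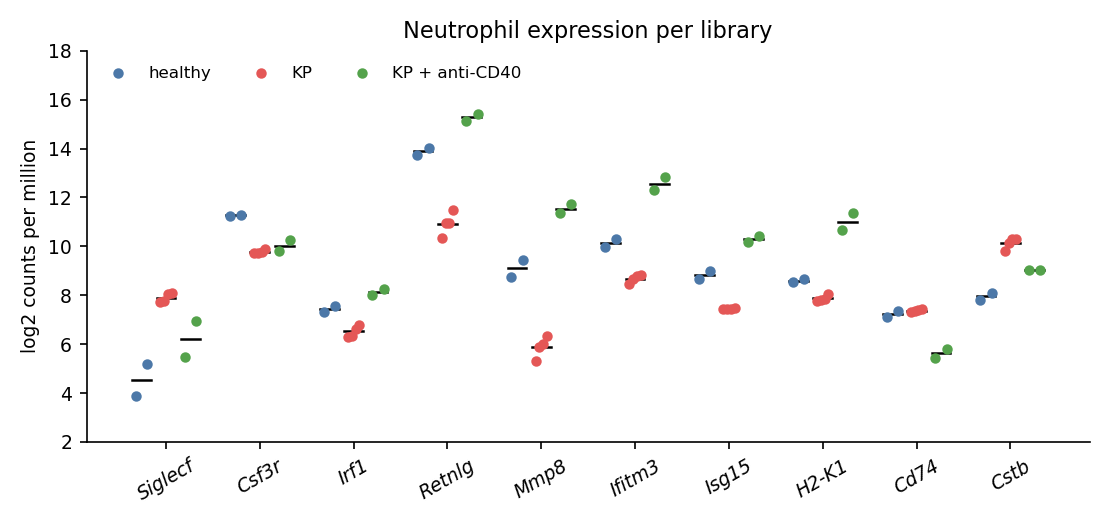
Log2 CPM of 10 genes in neutrophils (vertical axis), with 1 point per library in healthy, KP and treated groups and lines at group means. Siglecf was higher in KP than in healthy libraries (3.06) and lower in treated than in KP libraries (−1.53).

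Over all 5613 genes tested in neutrophils, 1449 were higher and 1388 lower with treatment by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3176 passed without adjustment. Treated and KP libraries were fully separated for 59.2% of genes, where chance gives 13.3%. With treated sums thinned to the KP totals 1141 genes were higher and 1047 lower, a comparison chosen after the data were seen, and 2092 of the calls were shared. In cells with at least 1000 UMIs 481 genes were higher and 426 lower of 1437 tested, with 35 to 69 neutrophils left per KP library.

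Treated neutrophils held more N1a and less N4 than KP neutrophils, 67.3% ± 6.64 against 6.90% ± 1.82 and 14.7% ± 11.1 against 52.8% ± 6.09 (SD; n = 2 and 4). N4 was 6.82% in the library of replicates 1 and 3 and 22.6% in that of replicates 2 and 4. N1b was 9.75% against 16.3%, N3 0.304% against 6.96%, N6 2.94% against 9.59%, N5 3.01% against 7.14% and N2 1.98% against 0.339%. The smallest exact permutation p was 0.0667 and the smallest adjusted p 0.0933, so none was called. With edgeR on cell counts, 6 states were called, all but N1b (adjusted p = 0.162), with N1a at adjusted p = 3.4e-07 and N4 at 0.00377. In cells with at least 1000 UMIs the differences in N1b (9.04 points), N3 (0.304) and N5 (0.456) turned, that in N4 was −4.10 points and that in N6 −74.0, with 38 N4 and 2 N1a cells left in KP libraries.

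Neutrophils were 75.7% ± 17.1 of treated CD11b+ cells (n = 2; 79.3% in KP, a difference that turned to 45.2 points in cells with at least 1000 UMIs and to 8.49 without treated replicates 1 and 3), 63.7% in the library of replicates 1 and 3 (exact 95% interval 62.7 to 64.7) and 87.8% in that of replicates 2 and 4 (87.1 to 88.5). DC2 was 0.358% ± 0.256 of treated and 3.42% ± 0.944 of KP cells, Mac4 5.30% ± 1.78 and 0.0276%, and T1 0.384% and 1.03%. These 3 types separated the groups (exact permutation p = 0.0667, adjusted 0.333) and were not called by that test. EdgeR on cell counts called DC2 (adjusted p = 0.0167) and Mac4 (adjusted p = 0.000603).

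On the surface of treated neutrophils Ly6C rose with a log2 change of 2.47 (SE 0.16; n = 2 in each group; adjusted p = 0.000157 by limma) and PDL1 with 1.71 (SE 0.17; adjusted p = 0.000681). SiglecF fell by 3.52 over all states (SE 0.47; adjusted p = 0.00222), while it differed by −0.81 within N1a and −0.33 within N4, which were not tested and were chosen after the data were seen. CD38 rose with 1.66, ICAM1 with 0.91, MHC class II with 0.52 and the growth factor receptor cKit with 0.42. CXCR4 fell by 2.06, F4/80 by 2.00, the co-stimulator CD86 by 1.72 and CD49d by 1.21. Ly6G, whose gene rose, stood at −0.24 (SE 0.10; limma adjusted p = 0.0850), not called. Of 20 antibodies 13 were called by limma, 7 with summed antibody counts and 8 with the replicate block. The smallest exact permutation p was 0.333. Antibody counts per neutrophil were lower in treated libraries, with medians of 182 to 220 against 1165 to 1876. The changes above are thus in the share of a cell's antibody counts, not in the counts themselves. Thinned to 100 counts per cell, CXCR4 (−0.061), CD86 (−0.58) and CD49d (0.042) were not called. Centred log ratios turned MHC class II to a called fall (−0.34, limma adjusted p = 0.0393). They also turned ICAM1 (−0.12), CXCR4 (0.20) and CD86 (0.012), none of them called.

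**Figure D5:**
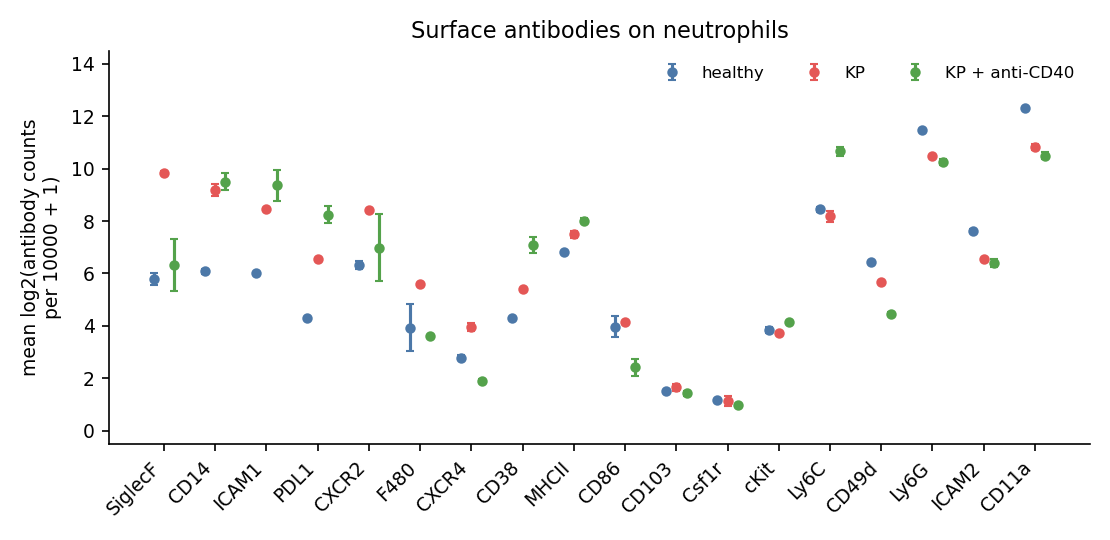
Mean log2 antibody count per 10000 in neutrophils (plus 1, vertical axis) in healthy, KP and treated groups, as points for group means with SD bars (n = 2 libraries each). SiglecF differed by 4.03 between KP and healthy lung and by −3.52 between treated and KP tumours, over all neutrophil states together.

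Mono3, a monocyte-labelled class of 35 to 68 cells per KP library and 298.5 and 58 cells (averaged over runs) in the treated libraries, was compared in the same way. With treatment Chil3 rose with 6.19 (SE 0.52), Ly6c2 with 5.26, Lcn2 with 5.18 (SE 0.34) and Naaa, an enzyme that breaks down fatty acid amides, with 4.38 (SE 0.34). Lpl, a lipase, rose with a ratio of 30.8 (8.52 to 255), Mmp8 with 4.63, Retnlg with 4.00 and Slfn4, an interferon-induced regulator of myeloid cells, with 3.57. Igfbp6, a growth factor-binding protein, fell by 3.01, Siglecf by 2.97, Bloc1s1, a subunit of lysosome-biogenesis complexes, by 2.82 and Id1, an inhibitor of transcription factors, by 2.22. Mono3 carried neutrophil transcripts, with S100a9 at 14.03 ± 0.13 log2 CPM in KP Mono3 and 15.51 ± 0.15 in KP neutrophils (SD, n = 4). Retnlg was at 13.09 in treated Mono3 and 15.28 in treated neutrophils.

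Interferon-stimulated genes rose in treated Mono3, 8 of 10 (10 over the list alone), with a median of 1.55 and camera adjusted p = 5.8e-06 (adjusted p = 0.205 with an estimated correlation), Bst2, which tethers virus particles, with 1.47, Isg15 with 1.43 and Ifitm3 with 1.16. Of 9 MHC class I genes 5 rose (8 over the list alone), with a median of 0.93 and camera adjusted p = 0.000714 (adjusted p = 0.248 with an estimated correlation), H2-K1 with 1.66, B2m with 1.22 and H2-D1 with 0.92. All 5 specific granule genes rose, with a median of 4.63 and camera adjusted p = 2.3e-11, a call that held with an estimated correlation (adjusted p = 0.0175). Cybb, an oxidase subunit, rose with 1.06 and Lyz2 with 1.44. S100a9 rose with 1.11 and Pglyrp1, a peptidoglycan-binding granule protein, with 0.88. In neutrophils 12 of 13 specific granule genes rose as well, and over 978 genes the treatment changes of both classes correlated at 0.665 (Pearson). A part of neutrophil RNA in the changes of treated Mono3 was not tested, so whether they arose in Mono3 is left open. Of 2 alveolar macrophage markers Chil3 was called, and 2 over the list alone (camera adjusted p = 0.00169; adjusted p = 0.205 with an estimated correlation).

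The remaining lists were not called in treated Mono3 by camera. Of 11 SiglecF-high genes 3 fell (4 over the list alone; adjusted p = 0.198), Cd63 by 0.97 and Csf1, the macrophage growth factor, by 1.67. Of 8 cytokine and NF-kB genes 1 rose and 2 fell (1 and 3 over the list alone; adjusted p = 0.321), Osm, a cytokine, with 1.84, Il1b falling by 1.15 and Ptgs2 by 1.36. Of 3 azurophil and progenitor genes Ctsc rose with 2.40, Calr with 1.59 and Srgn fell by 0.88 (adjusted p = 0.375). Both cell cycle genes measured, Hmgb2 (1.17) and Tubb5 (1.32), rose (adjusted p = 0.133). Of 10 stress genes Jun fell by 0.79, a call lost over the list alone (adjusted p = 0.653), and of 5 mononuclear phagocyte genes Ly6c2 rose and Apoe fell by 2.07 (adjusted p = 0.847). None was called among 3 interferon-gamma genes (0.847), 4 MHC class II genes (0.970), 7 hypoxia genes (0.847) and 1 B-cell marker (0.970).

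Of 991 genes tested in Mono3 129 were higher and 123 lower with treatment by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (2 against 4 libraries), and 382 passed without adjustment. The groups were fully separated for 41.4% of genes, where chance gives 13.3%. The count was 358 higher and 41 lower without the filter on low counts, 63 and 60 with the replicate block and 80 and 80 in the libraries with antibody counts. Of the 34 named calls 12 were lost under at least 1 setting, and 9 were lost with the replicate block.

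Between KP tumours and healthy lung, Mono3 gained Cd63 with a log2 change of 4.13 (SE 0.61; adjusted p = 0.000788 by edgeR's quasi-likelihood test) and Cxcl2 with 2.73 (SE 0.33; adjusted p = 0.000348). UMIs were found in KP libraries alone for Ltc4s, the leukotriene C4 synthase (69 UMIs, at least 14.1-fold), Id1 (52, at least 10.6-fold), Prss2 (51, at least 10.4-fold), C1qa, a complement subunit (46, at least 9.37-fold), Scimp, an adaptor of antigen-presenting cells (39, at least 7.94-fold), and Spp1, osteopontin (31, at least 6.31-fold). Siglecf rose with a ratio of 31.2 (5.35 to 1250). Mbp, known from myelin, fell by 3.29, Ly6c2 by 3.09, Ace, an angiotensin-converting enzyme of patrolling monocytes, and Retnlg both fell by 2.69, and Klra2, a lectin-like receptor, fell by 2.32. Pou2f2, a transcription factor, fell by 2.15, and Slpi, a protease inhibitor, and Apoc2, an apolipoprotein, both fell by 2.11.

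Of 11 SiglecF-high genes 7 rose in KP Mono3 (median 3.38, or 2.66 with bounds; camera adjusted p = 3.91e-05; adjusted p = 0.278 with an estimated correlation), Ccl3 with 3.38 and Cstb with 1.95. S100a9 fell by 0.79 and Pglyrp1 by 1.53. Of 5 specific granule genes 3 fell, Lcn2 by 1.90, Cybb by 1.71 and Lyz2 by 1.24 (camera adjusted p = 0.00176; adjusted p = 0.278 with an estimated correlation). Of 7 hypoxia and glycolysis genes 3 rose, Mif with 2.69, Ldha with 1.47 and Gapdh with 1.31 (camera adjusted p = 0.0249; adjusted p = 0.627 with an estimated correlation). Cytokine and NF-kB genes rose in 3 of 8, among them Il1rn with 2.72 and Ccrl2, a chemokine-binding receptor, with 1.99 (camera adjusted p = 0.157). Stress genes fell in 2 of 10, Dusp1 by 1.44 and Zfp36, an mRNA-destabilising protein, by 1.07 (camera adjusted p = 0.194). Of 9 MHC class I genes B2m fell by 0.73 and H2-D1 by 0.83 (camera adjusted p = 0.177), of 10 interferon-stimulated genes Ifitm3 fell by 1.18 (camera adjusted p = 0.514), of 3 interferon-gamma genes Fgl2 fell by 1.59, and of 5 mononuclear phagocyte genes 1 rose and 1 fell. None of the 4 MHC class II, 3 azurophil, 2 cell cycle, 2 alveolar macrophage and 1 B-cell genes was called. Mono3 carried neutrophil transcripts, and neutrophils were 36.6% of healthy and 79.3% of KP cells. A part of neutrophil RNA in these changes was not tested, so whether they arose in Mono3 is left open.

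Of 991 genes 122 were higher and 81 lower in KP Mono3 by edgeR's quasi-likelihood test (4 against 2 libraries), 347 passed without adjustment, and 42.1% were fully separated, where chance gives 13.3%. Without healthy replicate 1 28 genes were called, all of them among these 203, without healthy replicate 2 32 (31 of them shared) and without KP replicate 3 126 (121 shared). The count was 43 higher and 76 lower without the filter on low counts, 37 and 22 with the replicate block and 46 and 30 in the libraries with antibody counts. Of the 35 named calls, 25 were lost without healthy replicate 1 and 23 without healthy replicate 2.

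Mac1, a macrophage-labelled class, had enough cells in 3 KP libraries (20 to 26 cells) and both treated ones (631.5 and 58 cells, averaged over runs). With treatment Naaa rose with 3.61 (SE 0.47; adjusted p = 0.00329 by edgeR's quasi-likelihood test), Ly6e, an interferon-induced surface protein, with 2.50, and Ifitm3 with 2.28 (adjusted p = 0.0476). Sdad1, a ribosome assembly protein, rose with a ratio of 17.4 (4.81 to 144), AW112010, an interferon-induced transcript, with 2.63, Lgals3bp, a galectin-binding protein, with 2.02, Ctsc with 1.76 and Ifi27l2a, an interferon-induced gene, with 1.53. Cd74 fell by 1.61 (adjusted p = 0.0302), Ost4, a subunit that adds sugars to proteins, by 1.48, Atp5mpl, an ATP synthase subunit, by 1.44, Tomm6, a mitochondrial import subunit, by 1.34 and the non-coding RNA Malat1 by 1.06.

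Of 7 MHC class I genes 2 rose in treated Mac1 (5 over the list alone), B2m with 1.41 and H2-K1 with 1.22 (camera adjusted p = 0.000514; adjusted p = 0.458 with an estimated correlation). Of 7 MHC class II genes 1 fell (5 over the list alone), with a median of −1.24 (camera adjusted p = 0.000198; adjusted p = 0.458 with an estimated correlation). Of 5 interferon-stimulated genes 1 rose (2 over the list alone; camera adjusted p = 0.000954; adjusted p = 0.458 with an estimated correlation), and of 3 specific granule genes 0 (1 over the list alone; camera adjusted p = 0.044; adjusted p = 0.458 with an estimated correlation). Camera called no other list. Adjusted p was 0.124 for 3 azurophil genes, of which 1 rose, for 5 cytokine, 2 cell cycle and 10 stress genes, 0.172 for 2 alveolar macrophage genes and the platelet marker Pf4, and 0.255 for 12 SiglecF-high genes. It was 0.370 for 1 interferon-gamma gene, 0.821 for 11 mononuclear phagocyte genes and 0.823 for 9 hypoxia genes.

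Of 781 genes tested in Mac1 13 were higher and 6 lower by edgeR's quasi-likelihood test (2 against 3 libraries), 165 passed without adjustment, and 39.6% were fully separated, where chance gives 20%. DESeq2 called 28 higher and 41 lower, edgeR 120 and 19 without the filter on low counts, 37 and 40 with the replicate block and 0 and 1 in the libraries with antibody counts. Without KP replicate 1 the count was 15, without KP replicate 2 or KP replicate 3 it was 1, without the library of treated replicates 1 and 3 it was 56 and without that of replicates 2 and 4 it was 110.

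The treatment changes of neutrophils and of the other classes were compared within each library. Of 904 genes 31 changed more upward in neutrophils than in Mono3 and 24 less by limma with Benjamini-Hochberg adjustment (282 without adjustment), but only 4 and 3 with a prior count of 0.5. Ifitm6 differed by 4.63, Plac8, a lysosomal protein of myeloid cells, by 3.56, Ifitm3 by 2.93, H2-K1 by 1.74 and H2-D1 by 1.41, while Ccnd2, a cyclin, differed by −2.81, S100a10, a calcium-binding adaptor, by −2.80 and Lgals1, a galectin, by −2.13. Of 525 genes 19 changed more upward in neutrophils than in Mac1 and 0 less (179 without adjustment), Thbs1, a matrix protein, by 4.30, Anxa1, an anti-inflammatory annexin, by 4.25 and Ifitm3 by 2.39. These genes were chosen after their values were seen. No gene was called against Mac1 with any 1 KP library left out. From 3398 to 3666 genes passed the filter then, rather than 525, which makes the adjustment stricter, so these losses are not like for like. The calls against Mac1 were not kept without either treated library, where 642 and 683 genes were tested. Such fits leave 1 treated library. Against Mono3 the count was 0 without KP replicate 1, 10 without KP replicate 2, 6 without KP replicate 3 and 1 without KP replicate 4.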

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

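The tests of the mix of states and of transcript length were chosen only after their results had been seen, and the other tests of explanations were set before.

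A value was singled out where 1 library of a group of 4 lay far from the others by Dixon's 95% critical value. Chance sets apart about 1 in 20 groups, and of 98 values tested 6 were set apart, where 4.9 were expected. Among KP libraries 1 basophil was found, in replicate 3 (0.0573%, exact 95% interval 0.00145 to 0.319), and 1 Mac4 cell, in replicate 4 (0.110%, 0.00279 to 0.613). A single cell beside 3 libraries with none fixes the gap at 1 times the range, so these 2 values do not show that a library differed. Cd63 in neutrophils was lower in KP replicate 2, at 8.89 log2 CPM against 9.38 to 9.48, with a gap of 0.830 of the range. Socs1 was lower in the same library, at 4.75 against 5.37 to 5.49 (0.836), and Isg15 higher, at 7.50 against 7.44 to 7.45 (0.890). Ifit3 had no counts in KP replicate 4 and stood at −1.28 against 3.06 to 3.78 elsewhere (0.859).

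The treatment change differed between cell classes for 55 genes between neutrophils and Mono3 and for 19 genes between neutrophils and Mac1, by limma on the differences within libraries. Against Mono3, Canx, a chaperone of the endoplasmic reticulum, differed by −2.14 and mt-Cytb, a mitochondrial gene, by −1.93. Against Mac1, Tspo, a mitochondrial membrane protein, differed by 3.00 and Ifitm2 by 2.47. Against Mono3 the count was 7 with a prior count of 0.5, 0 without KP replicate 1 or either treated library, 10 without KP replicate 2, 6 without KP replicate 3 and 1 without KP replicate 4. No call against Mac1 was left with any 1 KP library left out, where 3398 to 3666 genes were tested rather than 525. The calls were not kept without either treated library, where 642 and 683 genes were tested and 1 treated library remained.

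The higher share of N1a and lower share of N4 in treated neutrophils may reflect the treatment or the making of the libraries. Treated cells thinned to the UMI totals of KP neutrophils and relabelled from healthy and KP profiles were at least 57.2% N1a, while held-out KP libraries were 6 to 10% N1a (SD 1.80), which rules out UMIs per cell as the whole cause. Over all UMI minima up to 1000 the ratio of N1a to N4 cells in KP libraries reached 0.157, against 2.78 and 10.6 in the treated libraries, but no treated cell held fewer than 1695 UMIs, which these minima did not reach, so a higher UMI minimum stays open. The labels name no batch, but the number of KP libraries with the depth of the treated ones was 0, so a batch, if there was one, and treatment cannot be told apart.

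The rise of interferon-stimulated genes in treated neutrophils could come from the antibody, from the mix of states or from free RNA of mononuclear phagocytes, which the CD11b gate does not remove. Within N1a, N1b and N4 the lowest median log2 change of the list was 2.00, so the mix of states alone does not account for the rise of the members measured there. Free RNA would have to make up 152% and 324% of neutrophil RNA for the median interferon gene, while the median of 11 mononuclear phagocyte genes, 7 of which also passed the filter in neutrophils, allowed 2.12% and 2.68%. C1qa allowed 1.14% and 2.04% and Apoe 3.42% and 2.68%, and the share needed was at least 71.8 times the share allowed, which rules out this source. The labels name no batch, but the number of untreated libraries with the depth of the treated ones was 0, so a batch, if there was one, and treatment cannot be told apart.

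Lower short transcripts in treated libraries could come from the cells or from the making of the libraries. The difference between short and long transcripts closest to 0 within N1a, N1b, N4, Mono3 and Mac1 was −0.58. A change in the mix of neutrophil states alone thus does not account for it. Over fewer genes it was −0.72 in N1a, −0.67 in N1b and −0.73 in N4, against −1.11 in all neutrophils, so the mix may account for part. The difference was −0.48 (SE over genes 0.11) in NK and T1 cells, the value closest to 0 of neutrophils, Mono3, Mac1 and lymphoid cells. A length bias between the treated and the other libraries would give such values. The untreated groups also differed, since the same difference between KP and healthy libraries was 0.59 in neutrophils and 0.40 in Mono3. Treated libraries were not compared with healthy ones. Genes of ribosomal proteins had medians of −0.92 in neutrophils and −0.35 in NK and T1 cells, but −0.050 in Mono3 and 0.15 in Mac1. Their lengths were not compared, so a length bias is not settled. No biological explanation was tested for this pattern.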

How the results depend on the processing

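The settings for thinned sums, single states, merged runs and thinned antibody counts were chosen only after results had been seen, and the other settings were set before. Where a value below moved, the cause was not tested, except that smaller sets of cells, genes or libraries have less power by construction. The treated libraries held far more UMIs per cell than the others, and the healthy group rested on 2 libraries. A library left alone in its group was assumed to vary like the other groups. Doublet removal was not run, since the caller marked too few cells to be used, and cells with at least 1000 UMIs were not run for genes of KP against healthy lung or of other myeloid cells, where too few cells were left.

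Of 51 named calls in KP against healthy neutrophils, 39 kept direction and call under every setting, 12 were lost under at least 1 and 0 turned. Of 51 in treated against KP neutrophils, 27 held throughout, 18 were lost and 15 turned under at least 1. In Mono3, 22 of 34 held for treatment and 8 of 35 for KP against healthy, and in Mac1 0 of 15. No named gene turned in Mono3 or Mac1. Every turn of a named gene came in cells with at least 1000 UMIs or in single states. For genes these settings were run in treated against KP neutrophils alone, so the numbers that turned are not like for like. Calls in neutrophils kept to within 1.5 times the main count under DESeq2 (1197 higher and 1522 lower for treatment, 997 and 1014 for KP against healthy), RLE (1299 and 1600, 1177 and 1041), the 2 groups alone (1551 and 1514, 1160 and 1040), the libraries with antibodies (1262 and 1076, 790 and 1105), no filter (2146 and 1319, 1045 and 1211), 4 treated libraries (1887 and 1821) and 1 run of each pair (1448 and 1381).

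With each library left out, edgeR's calls in neutrophils ran from 2243 to 3259 for treatment and from 1078 to 2173 for KP against healthy. In Mono3 they ran from 192 to 317 and from 28 to 177, and in Mac1 from 1 to 110, with 15 without KP replicate 1, 56 without treated replicates 1 and 3 and 110 without treated replicates 2 and 4. Lists called by camera numbered 7 under each for treatment and 6 to 7 for KP against healthy. Antibodies called by limma numbered 9 to 16 and 12 to 13. With each KP library left out, genes whose change differed from Mono3 numbered 0 to 10 and from Mac1 0. For Mac1 3398 to 3666 genes were tested then, rather than 525. The calls against Mac1 were not kept without either treated library, where 642 and 683 genes were tested and 1 treated library remained. Without treated replicates 1 and 3 the neutrophil share turned to 8.49 points above KP, and camera turned the stress list (adjusted p = 0.967). The mononuclear phagocyte list turned without treated replicates 2 and 4 (camera adjusted p = 0.956) and without KP replicates 1 (0.943) and 3 (0.839), each left out alone, and was at 0.791 without KP replicate 4. The Csf1r antibody ran from −0.26 to 0.0015 for treatment and from −0.19 to 0.075 for KP against healthy, and CD86 from −0.13 to 0.45 for KP against healthy.

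Whether the replicate numbers pair the libraries could not be told. Over 1844 genes the deviations of same-numbered libraries correlated at 0.224 between healthy and treated, and at 0.137 and 0.0682 between healthy and KP. Between KP and treated they correlated at −0.0551 and 0.127. Each merged treated library took its first number, and by its second number the correlations with KP were −0.0486 and −0.217. In a group of 2 libraries the deviations are mirror images, so few of these values are independent and they cannot decide on pairing. With the replicate block the calls were 1178 higher and 1119 lower in treated neutrophils and 915 and 1052 in KP against healthy. They were 123 in Mono3 for treatment, 59 in Mono3 for KP against healthy, 77 in Mac1 and 8 antibodies for treatment. The cell cycle list turned with the block in KP against healthy (camera adjusted p = 0.883), and edgeR on cell counts with the block called 1 type for treatment.

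The counts reported were 129 higher and 123 lower in treated Mono3, 122 and 81 in KP against healthy Mono3 and 13 and 6 in Mac1. Without the filter on low counts 399 genes were called in treated Mono3 (358 higher and 41 lower), 119 in KP against healthy Mono3 (43 and 76) and 139 in Mac1 (120 and 19). With the libraries with antibodies alone they were 160, 76 and 1, and with DESeq2 69 in Mac1 (28 and 41).

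In cells with at least 1000 UMIs 907 genes were called in treated neutrophils, against 1449 higher and 1388 lower in all cells. That minimum left 35 to 69 neutrophils per KP library and changed their mix of states. S100a8 (−0.16), Lyz2 (−0.50), Ccl4 (0.98), Ptgs2 (0.31) and, called on the other side, Ctsc (−1.10) turned. So did the differences in share of neutrophils (45.2 points), N1b (9.04), N3 (0.304) and N5 (0.456) with treatment, and basophils were 0 in KP and healthy lung.

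Within N1a cells 350 genes and 4 lists were called for treatment. S100a8 (−0.42), S100a9 (−0.035), Cstb (0.33), Hmgb2 (−0.052), Junb (−0.21), Fos (−0.039), Dusp1 (−0.57) and Csf3r (−0.65) turned. Of these, S100a8, Dusp1 and Csf3r were called within N1a. By camera the azurophil (adjusted p = 0.729), hypoxia (0.319), stress (0.184) and mononuclear phagocyte (0.0727) lists turned, and the call of the SiglecF-high list was lost (0.914). Within N1b cells 626 genes were called. S100a8 (−0.25), Cstb (0.64), Ccl3 (1.17), Ccl4 (0.55), Il1rn (0.81), Mif (0.032), Hmgb2 (−0.21), Junb (−0.14), Fos (−0.024), Dusp1 (−0.31), Ighm (−1.01) and Csf3r (−0.45) turned. Of these, S100a8, Cstb, Ccl3, Il1rn and Csf3r were called within N1b. By camera the azurophil (adjusted p = 0.576), SiglecF-high (0.110), cytokine (0.900), hypoxia (0.613), stress (0.576), B-cell (0.613) and mononuclear phagocyte (0.477) lists turned. Within N4 cells 622 genes and 11 lists were called. S100a8 (−0.22), Ccl3 (0.73), Ccl4 (0.21), Ptgs2 (0.16), Ighm (−0.10), Car4 (0.28) and Csf3r (−0.55) turned. Of these, Ccl3 and Csf3r were called within N4. By camera the SiglecF-high (adjusted p = 0.826), cytokine (0.0438), cell cycle (0.967) and B-cell (0.869) lists turned.

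With an estimated correlation camera called 0 lists in neutrophils in either comparison. For treatment the adjusted p was 0.0535 for interferon-stimulated and 0.273 for SiglecF-high genes, and for KP against healthy 0.232 and 0.109. It called 1 list in Mono3 for treatment, 0 in Mono3 for KP against healthy and 0 in Mac1. Fry turned the cell cycle list for treatment (adjusted p = 0.953), and with thinned sums camera turned the mononuclear phagocyte list (0.780). EdgeR on cell counts called 2 types for treatment and 3 for KP against healthy, and 6 states in each.

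Summed antibody counts gave 7 calls for treatment and turned CXCR4 (0.87), Csf1r (1.34), ICAM2 (0.026) and CD103 (1.31), and CD103 for KP against healthy (−0.24). Of these turns, CD103 for treatment was called by limma. Centred log ratios turned CD14 (−0.70), CXCR4 (0.20), Csf1r (1.52), MHC class II (−0.34), ICAM1 (−0.12), CD103 (1.35) and CD86 (0.012) for treatment, and CD103 (−0.60) and CD86 (−0.45) for KP against healthy. With that scaling limma called CD14, Csf1r, MHC class II and CD103 on the turned side for treatment. It called CD103 and CD86 so for KP against healthy. Thinning to 100 counts turned Csf1r (0.39), ICAM2 (0.84), CD103 (0.50) and CD49d (0.042) for treatment, and CD103 (−0.045) and CD86 (−0.041) for KP against healthy. After thinning, Csf1r, ICAM2 and CD103 were called on the turned side for treatment. With a prior count of 0.5 limma called 7 genes whose change differed between neutrophils and Mono3.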

Other observations

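The comparisons within states and in lymphoid cells were chosen only after results had been seen.

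Genes of 3 other lists also differed between treated and KP libraries within neutrophil states, by edgeR's quasi-likelihood test. MHC class I genes rose in 8 of 8 measured in N1a, 13 of 13 in N1b and 10 of 14 in N4. MHC class II genes fell in 1 of 1, 1 of 1 and 4 of 4, so that N1a and N1b rested on 1 gene, with a median of −2.58 in N4. Of 6 mononuclear phagocyte genes in N4 2 fell and 0 rose (median −0.96), while 1 of 1 rose in N1a, and 1 rose and 1 fell of 3 in N1b. Whether the class II transcripts came from neutrophils is thus left open within states too. Specific granule genes rose in 8 of 10, 7 of 9 and 5 of 9, with medians of 2.82, 2.49 and 1.28. The medians of interferon-stimulated genes were 2.61, 2.64 and 2.00. In each state the filter could admit a gene through the treated libraries alone, so rises are partly set by the filter.

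On the surface, PDL1 differed between treated and KP neutrophils by 3.79 within N1a and by 1.41 within N4, CD38 by 2.82 and 1.56, ICAM1 by 2.64 and 0.91 and Ly6C by 2.22 and 1.49. These differences within states were not tested. Cd274, the gene of PDL1, stood at 0.45 in treated against KP neutrophils (SE 0.19; adjusted p = 0.0593 by edgeR's quasi-likelihood test), a gene chosen after its value was seen.

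The 2 treated libraries differed from each other in mononuclear cells. Mono1 was 5.74% in the library of replicates 1 and 3 (exact 95% interval 5.28 to 6.25) and 0.0760% in that of replicates 2 and 4 (0.0279 to 0.165). MonoDC was 4.70% (4.26 to 5.15) and 0.0506% (0.0138 to 0.130), and Mac1 7.09% (6.57 to 7.65) and 0.734% (0.558 to 0.948). Mac4 was 6.56% (6.05 to 7.09) and 4.04% (3.62 to 4.50), and both libraries held more of it than any KP library.

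In NK and T1 cells together, 46 genes were higher and 49 lower of 950 tested with treatment by edgeR's quasi-likelihood test, in libraries with at least 15 such cells. The 1 interferon-stimulated gene measured there rose with a log2 change of 2.97.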
